A study of Homo sapiens with 8 samples.

How the data were processed

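PolyA RNA was sequenced from 8 libraries of IMR90, a human lung fibroblast line, at passage 28. Per the labels' protocols, cells grew in DMEM with 10% serum under 3% oxygen and 5% carbon dioxide, were seeded at 300K cells per mL, and on the following day received DMSO or Nutlin-3a at 3 µg/mL. Nutlin-3a blocks the binding of MDM2, a ubiquitin ligase, to p53. There were 4 groups of 2 libraries, which were DMSO and Nutlin-3a for 6, 9 and 12 h. How long the DMSO cultures were kept, when each group was harvested, and whether replicates came from separate cultures are not given in the sources used here, so p-values measure only the spread between these samples, which may be technical. Libraries were made with a kit that marks the strand.

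Per the submitters' processing notes, reads were handled with STAR and DESeq2 on the genome build hg19, with no versions listed. The counting tool, its strand setting and the annotation are not given in the sources used here. The authors deposited a table of gene counts divided by a size factor for each library, which is a normalized signal rather than raw counts. It listed 18216 genes and 3 further entries for reads that were ambiguous, lay in no annotated feature or aligned in several places. Those entries held 28.2 to 29.1% of each library's total and were left out of library sizes and tests. In the table, genes had a sum of at least 10 reads over the libraries. The authors also deposited 3 tables of DESeq2 results, with log2 fold changes, a Wald statistic score, p-values and adjusted p-values of DMSO against each Nutlin-3a time. Their fold changes are DMSO over Nutlin-3a, and the sign was turned here.

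Each library's values were whole multiples of the value of 1 read, so reads could be recovered. All values came out whole within a tolerance of 1e-06 (100% in each library). In the 9 h replicate 1 library this step lies so close to 1 that an automatic test for it gives no verdict, and the same arithmetic was used. Gene reads per library ranged from 21.9 to 33.6 M (1e6), and 3 reads, taken as the floor, correspond to a normalized count of 2.46 to 3.75. This floor covers counting error only, since PCR copies were not marked.

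The main test was limma 3.58.1 with an intensity trend in R 4.3.3, on log2(normalized count + 1), in a single fit of all 8 libraries with 4 residual and 15.5 prior degrees of freedom. Fold changes are on this scale, which understates changes of genes with low counts. Genes with a value of at least 10 in at least 2 libraries were tested, 14074 in all. Each Nutlin-3a time was compared with DMSO, the times with one another, and the 4 groups together by an F test. P-values were adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. Genes so called are described as having risen or fallen. A value with ± is a mean with its SD over n = 2 libraries for normalized counts, and a log2 change with its standard error otherwise. Groups of 2 are too small for an exact permutation test to reach the threshold, since the smallest p is 0.333.

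The design, the tests, the rule for naming genes and 26 gene lists were fixed before the data were examined. The lists were p53 targets in arrest and feedback, in apoptosis and death receptors, in DNA repair, and in metabolism, redox and autophagy, p53-linked long non-coding RNAs, G1/S and DNA replication genes, G2/M and mitosis genes, and secreted inflammatory and senescence-associated factors. Further lists were NF-kB feedback, interferon-stimulated, ATF4 and unfolded protein response, cholesterol synthesis, extracellular matrix, TGF-beta and contractile, immediate early, ribosome biogenesis, hypoxia-response, lysosome, ribosomal protein and reference housekeeping genes. Markers of fibroblasts and of epithelial, endothelial, immune, and smooth muscle or pericyte cells were also listed. A list of mitochondrially encoded genes had 0 members in the table, so 25 lists were tested. Lists were compared with all other tested genes by camera with a preset correlation of 0.01, and again with an estimated correlation and with fry. With an estimated correlation camera also rests on only the 4 residual degrees of freedom. A call lost with it therefore need not come from correlation between genes. For metabolism targets (−0.0309) and fibroblast markers (−0.0175) the estimate lay below the preset value. Adjusted p-values of lists are over the 25 lists of a comparison. Counts of members are over all genes tested, with the count adjusted over the list alone beside them. A list of clock output genes was added after values had been seen.

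The naming rule took, for 6, 9 and 12 h against DMSO and for 12 h against 6 h, the 8 largest increases and the 8 largest decreases among called genes with a mean of at least 50 and groups that did not overlap. It also took genes fixed beforehand, MDM2 and CDKN1A among them, and from each list up to 4 members with the smallest p at 12 h and up to 2 called members that went against the majority. It named 141 genes, of which 5 are not reported here, and all 141 enter the counts of named genes and of changed calls. Those written out in the results were picked from the 141 after their values had been seen. Genes that tell the sex of a donor were not named.

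Alternatives were other pseudocounts (0.5 and 5), no filter on low values or a mean of at least 50, TMM and quantile scaling, no intensity trend, only the 2 groups compared, the replicate number as a block, each library left out, and edgeR 4.0.16 or DESeq2 1.42.0 on the recovered reads. A correction of each library for transcript GC content (a spline with 4 degrees of freedom over 13613 genes) and weights for each group were added after seeing the data. With a library left out, its group has 1 sample, which is assumed to vary like the others. Shared controls were simulated 20 times with unchanged groups. The DMSO pair and the 6 h pair were each also divided, 1 library to each of 2 comparisons, after seeing the data.

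The tests were tried on reads simulated from the gene means, spread and depth of the real libraries. All simulated groups had the same spread, unlike the real DMSO pair, so the shares of wrong calls may differ in the real data. At 12 h against DMSO, over 13903 genes, limma recovered 42, 80, 86 and 98% of genes changed 1.25-, 1.5-, 2- and 4-fold, and 3.77% of its calls were wrong. For edgeR these were 42, 78, 86 and 98%, with 6.75% of 163 calls wrong, above the threshold. These shares come from a single draw with 50 genes changed at each fold. In the real data 39.9% of genes were called at 12 h, so the shares recovered and wrong need not carry over. In a separate simulation with 1 list raised 1.5-fold, camera called that list and 0 of 19 others at 12 h. Genes were drawn independently, so this could not show an effect of correlation between genes. GC content, length and strand of genes came from a GRCh38 annotation matched by symbol, so no coordinates are given. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.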

Results

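RNA levels were compared between IMR90 lung fibroblasts treated with DMSO and with Nutlin-3a, a compound that frees p53 from MDM2, for 6, 9 or 12 h (n = 2 libraries per group). The design asks which transcripts differ under Nutlin-3a and how this differs with exposure time. A single DMSO group, whose culture time is not given, served all Nutlin-3a times. Changes with exposure therefore cannot be told from changes with culture or harvest time. Cells without p53 were not among the samples. Gene reads (M, 1e6 reads) amounted to 27.9 and 25.3 M in the DMSO libraries (replicates 1 and 2), 21.9 and 28.6 M at 6 h, 27.7 and 30.02 M at 9 h, and 33.6 and 26.3 M at 12 h. COL1A1, a fibrillar collagen chain, took 1.59 to 2.15% of gene reads. The first principal component held 50.9% of the variance and the second 19.5%. The 2 DMSO libraries lay farther apart than the other pairs, with an SD of the log2 difference of 0.147 over 9568 genes, against 0.0972 at 6 h, 0.0862 at 9 h and 0.0882 at 12 h. Chi-square per degree of freedom, which allows for counting error only and can grow with depth, was 7.35, 2.51, 1.94 and 2.15 for these pairs.

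After 6 h, 5 of the 8 genes with the largest increases under the naming rule were members of a p53 target list, namely GDF15, BTG2, CDKN1A, ACER2 and MDM2, a share that was not tested against chance. GDF15, a stress-induced cytokine, rose from a normalized count of 196 ± 14.4 to 4518 ± 96.7, a log2 change of 4.52 ± 0.06, and BTG2, an antiproliferative gene, by 4.34 ± 0.06. CDKN1A, which encodes the CDK inhibitor p21, rose by 3.47 ± 0.04 (11.1-fold), and MDM2 by 3.03 ± 0.06 (8.19-fold). ACER2, a ceramidase, rose by 3.04 ± 0.19. INPP5D, a lipid phosphatase, had normalized counts of 1.95 and 4.30 in the DMSO libraries, near the floor, and 60.6 ± 2.60 at 6 h. The largest decreases included replication and cell-cycle genes. The log2 change was −2.44 for FAM111B, −2.24 for ZNF367, −2.17 for CCNE2 (cyclin E2), −2.14 for E2F8 and −2.05 for CDC6, an origin licensing factor.

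In all, 2263 genes rose and 2897 fell at 6 h among 14074 tested, of which 235 rose and 190 fell at least 2-fold. The edgeR test on recovered reads gave 2383 and 2702, and the deposited tests of the authors 1607 and 2254. The main fit assumes a common spread, although the DMSO pair lay farther apart than the others. With only the 2 groups compared 1734 rose and 2388 fell, with group weights 1899 and 2457, and without an intensity trend 1651 and 2206. Without 6 h replicate 1, 1494 genes rose.

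After 9 h, 2273 genes had risen and 2691 had fallen. SULF2, an extracellular sulfatase, was 17.0-fold above DMSO (log2 4.08 ± 0.14) and CYFIP2, a regulator of actin, 15.4-fold (3.94 ± 0.09), beside BTG2 (4.29 ± 0.06), GDF15 (4.07 ± 0.06) and CDKN1A (3.85 ± 0.04). ZNF367 (−3.67 ± 0.15), CCNE2 (−3.65 ± 0.13) and FAM111B (−3.61 ± 0.12) were among the largest decreases. At least 2-fold changes were seen for 210 genes that rose and 380 that fell. The edgeR test gave 2547 and 2558 genes, and the deposited tests of the authors 1587 and 2180. With only the 2 groups compared 1799 rose and 2373 fell, with group weights 1981 and 2449, and without an intensity trend 1579 and 2107. Without 9 h replicate 1, 1419 genes rose, and without replicate 2, 1430.

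After 12 h, 2603 genes had risen and 3007 had fallen, 234 and 510 of them at least 2-fold. SULF2 reached a log2 change of 4.48 ± 0.14, CYFIP2 4.22 ± 0.09, BTG2 4.15 ± 0.06, CDKN1A 3.90 ± 0.04 (71666 ± 1125 normalized counts against 4812 ± 201) and MDM2 3.13 ± 0.06. ZNF367 (−3.96 ± 0.15), E2F8 (−3.94 ± 0.17) and FAM111B (−3.85 ± 0.12) were lowest among the named genes. The edgeR test gave 3006 and 2817 genes, and the deposited tests of the authors 1868 and 2502. With only the 2 groups compared 2211 rose and 2710 fell, with group weights 2321 and 2787, and without an intensity trend 1928 and 2462. In the main test genes that rose were 46.4% of those called, against 57.6% after quantile normalization. Without 12 h replicate 2, 1699 genes rose.

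**Figure D1:**
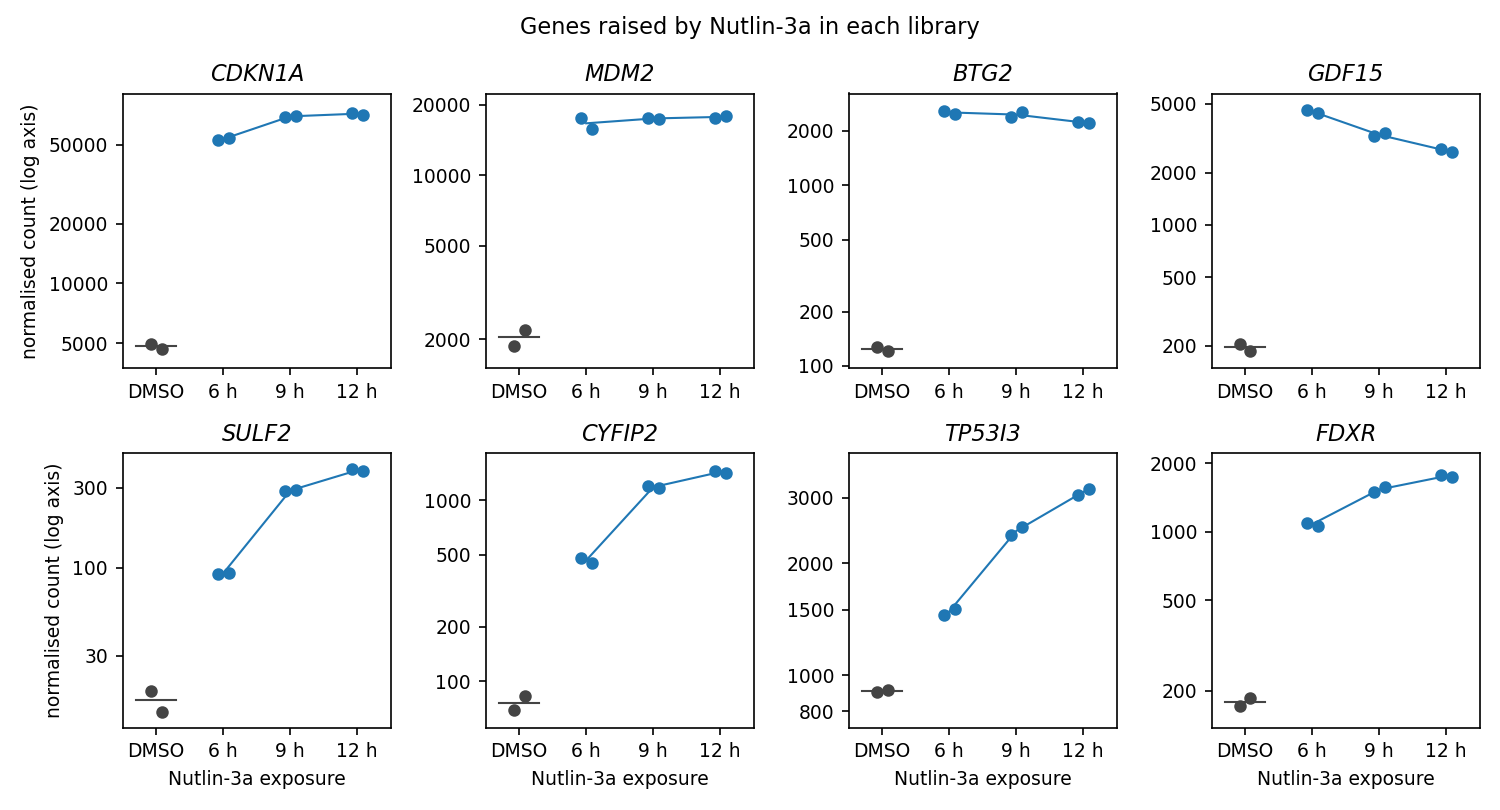
Normalized counts (log axis) of 8 genes that rose in each library, by exposure, where points are libraries and lines join the group means of Nutlin-3a libraries. CDKN1A rose from a mean of 4812 in DMSO to 71666 at 12 h.

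The p53 target lists for arrest, apoptosis and metabolism rose at each time with either correlation, and those for DNA repair and long non-coding RNAs only with the preset one (estimated correlation, adjusted p = 0.183, 0.206 and 0.253, and 0.101, 0.118 and 0.156). Of 24 targets in arrest and feedback, 22, 21 and 21 rose at 6, 9 and 12 h (22, 21 and 21 adjusted over the list alone), with median log2 changes of 1.32, 1.40 and 1.45. At 12 h 1 member fell, TP53I11 (−0.25 ± 0.06), and adjusted over the list alone 1 fell at 9 and at 12 h. Of 21 targets in apoptosis and death receptor signalling, 17 rose at each time and 1, 1 and 2 fell (18, 17 and 17 rose and 1, 2 and 2 fell adjusted over the list alone). They included the death receptors FAS (1.77, 1.86 and 1.84) and TNFRSF10B (1.85, 1.93 and 1.88), and the mitophagy gene SPATA18 (1.74, 2.41 and 2.67). TP53I3, an oxidoreductase, rose by 0.71, 1.43 and 1.78. The members that fell at 12 h were SIVA1, a proapoptotic gene (−0.42 ± 0.09), and BID, a BH3-only protein (−0.16 ± 0.06). The call of BID at 12 h was lost without DMSO replicate 1 (−0.11), 9 h replicate 1 or 2 (−0.16 each), or 12 h replicate 1 (−0.17) or 2 (−0.16). It was also lost with TMM (−0.14) or quantile scaling (−0.10), without a trend, with only the 2 groups, with group weights (−0.16 each), and with edgeR (−0.14), DESeq2 or the deposited tests (−0.16 each). The SIVA1 call at 12 h was lost without a trend (adjusted p = 0.0536). Calls were gained without DMSO replicate 2 for BID (−0.16 at 6 h and −0.20 at 9 h) and TP53I11 (−0.16 and −0.20), and without DMSO replicate 1 for SIVA1 at 9 h (−0.34). At 9 h they were also gained with GC correction for BID (−0.17), TP53I11 (−0.19) and SIVA1 (−0.23), and with a mean of at least 50 for BID (−0.15).

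Of 20 targets in metabolism, redox and autophagy, 15, 15 and 13 rose (16, 15 and 15 adjusted over the list alone) and 0 fell. FDXR, the ferredoxin reductase of mitochondria, rose by 2.58, 3.09 and 3.29, and TIGAR, a fructose bisphosphatase, by 1.89, 1.81 and 1.84. These 3 lists were called at each time by camera and with an estimated correlation (adjusted p = 0.00664, 0.00792 and 0.0106 for arrest, 0.0121, 0.0128 and 0.0163 for apoptosis, 0.0121, 0.0104 and 0.0131 for metabolism).

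Of 10 DNA repair targets, 5, 5 and 6 rose and 2 fell at each time (7, 6 and 6 rose and 3, 2 and 2 fell adjusted over the list alone). RRM2B, a ribonucleotide reductase subunit, rose by 1.56, 1.94 and 2.04 and DDB2, a sensor of UV lesions, by 1.01, 1.37 and 1.38, while FANCC, a Fanconi anaemia protein, fell at each time (−0.47, −0.70 and −0.80). Of 8 tested p53-linked long non-coding RNAs, 6, 7 and 7 rose (6, 7 and 7 adjusted over the list alone), among them MIR34AHG, the host transcript of miR-34a (1.51, 1.27 and 1.35), and NEAT1, the scaffold of paraspeckles (1.197, 0.63 and 0.89).

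Cell-cycle genes fell at each time and fell further with time. Of 50 G1/S and DNA replication genes, 49 fell at 6 h and 50 at 9 and 12 h, with medians of −1.10, −1.67 and −2.13. Of 52 G2/M and mitosis genes, 51 fell at 6 h and 52 at 9 and 12 h, with medians of −0.67, −1.39 and −1.997. Adjusted over the list alone, the counts were 49, 50 and 50, and 51, 52 and 52. MCM2, a subunit of the replicative helicase, had log2 changes of −1.32, −2.09 and −2.57, CCNA2 (cyclin A2) −0.95, −1.80 and −2.38, and MKI67, the gene of the proliferation marker Ki-67, −0.85, −1.68 and −2.52. Both lists held their calls with an estimated correlation (adjusted p = 0.00354, 0.00120 and 0.00125 for both lists). At 6 h the G1/S list had reached 55.1% of its mean 12 h change and the G2/M list 33.3%, and at 9 h 81.9 and 69.1%. The mean of the G2/M list lay above that of the G1/S list by 0.485 ± 0.0104 at 6 h, 0.329 ± 0.0256 at 9 h and 0.0915 ± 0.00627 at 12 h, relative to DMSO (SD, n = 2), a difference that an exact permutation test of 2 against 2 cannot call (smallest p = 0.333).

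**Figure D2:**
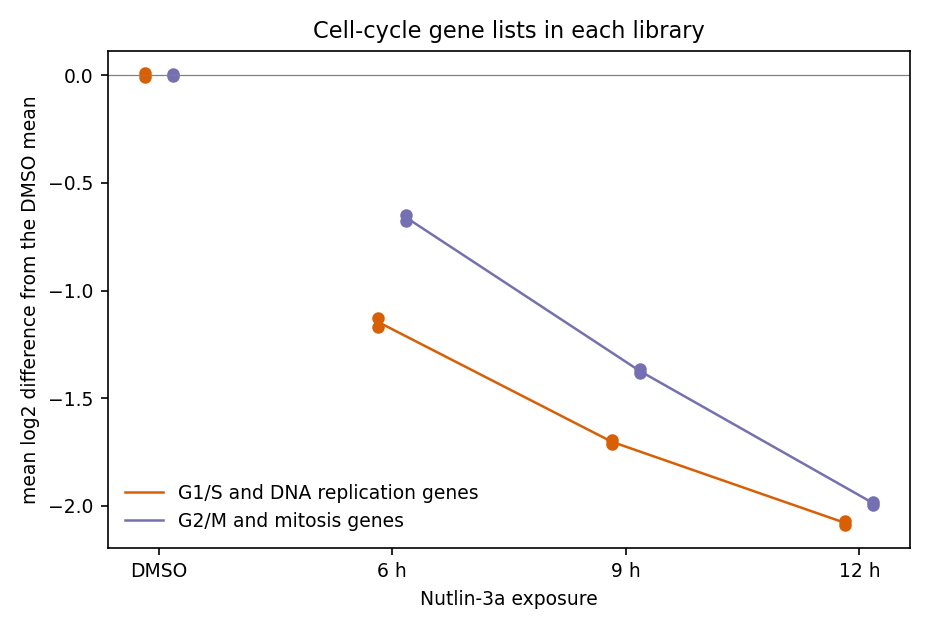
Mean log2 difference from DMSO of the G1/S and the G2/M list in each library, by exposure, where points are libraries and lines join the means of Nutlin-3a groups. The lists are 0.485 apart at 6 h and 0.0915 apart at 12 h.

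Further lists were called against DMSO. Of 35 ribosome biogenesis genes, 25, 26 and 28 fell and 1, 0 and 1 rose (26, 28 and 30 fell and 1, 0 and 2 rose adjusted over the list alone), with medians of −0.22, −0.30 and −0.37. They included NOP56 (−0.55, −0.76 and −0.80) and NOLC1 (−0.60, −0.71 and −0.74). The list lost its call with an estimated correlation (adjusted p = 0.0737, 0.0556 and 0.0627). The member that rose at 12 h among those named was RRS1 (0.20 ± 0.05), whose call was lost without 12 h replicate 1 (0.19). Of 31 ATF4 and unfolded protein response genes, 19, 22 and 19 rose and 2, 1 and 6 fell (19, 23 and 20 rose and 2, 2 and 8 fell adjusted over the list alone). The chaperone gene HSPA5 rose by 0.57 at 9 h and 0.67 at 12 h, and DDIT4, an mTOR inhibitor, by 1.37, 0.96 and 1.04. With an estimated correlation this list was called at 6 and 9 h (adjusted p = 0.0183 and 0.0274) and not at 12 h (adjusted p = 0.124).

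Of 25 secreted inflammatory and senescence-associated factors, 14, 11 and 10 rose and 6, 4 and 4 fell, with the same counts adjusted over the list alone. ANGPTL4 rose by 2.51, 1.36 and 0.88 and the cytokine LIF by 1.23, 0.79 and 0.88, while the chemokines CCL2 (−0.81, −0.84 and −0.67) and CXCL8 (−1.05, −1.04 and −1.15) fell. With an estimated correlation the list was called at 6 h (adjusted p = 0.0493) and not at 9 and 12 h (adjusted p = 0.1004 and 0.167), and without 12 h replicate 1 its 12 h call was lost (adjusted p = 0.0669). Quantile normalization ended its 9 and 12 h calls (0.132 and 0.178) and GC correction its 12 h call (0.0530). Of 28 hypoxia-response genes, 16, 13 and 10 rose and 2, 2 and 4 fell (17, 13 and 10 rose and 2, 2 and 4 fell adjusted over the list alone), VEGFA by 0.99, 0.58 and 0.46. This list held with an estimated correlation at 6 h (adjusted p = 0.0405) and not later (adjusted p = 0.0935 and 0.253). Its 12 h call was lost without DMSO replicate 1 (adjusted p = 0.0769), 12 h replicate 1 (0.0771), 6 h replicate 1 (0.0518) or 2 (0.0516), or 9 h replicate 1 (0.0512) or 2 (0.0510), and with quantile normalization (0.142).

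Extracellular matrix genes were called at 9 and 12 h by camera with the preset correlation only, since the calls were lost with an estimated one (adjusted p = 0.368 and 0.357) and with quantile normalization (0.253 at both times). Of 35 members, 7, 17 and 22 rose and 4, 1 and 2 fell (6, 21 and 24 rose and 3, 1 and 4 fell adjusted over the list alone), with a median of 0.15 at 12 h. COL5A1 rose by 0.30 and 0.32 at 9 and 12 h, and FBN2 (fibrillin 2) by 0.26 and 0.41. After quantile normalization the medians of the list were 0.02. COL1A1 (0.32 at 12 h) and COL1A2 (0.34) lost their calls after that scaling (0.00 and 0.10), which fixes the values of top-ranked genes. Of 32 lysosome genes, 17, 18 and 14 rose and 0, 1 and 3 fell (17, 18 and 14 rose and 0, 2 and 3 fell adjusted over the list alone). This call was lost with an estimated correlation (adjusted p = 0.0737, 0.0934 and 0.253) and at 12 h without DMSO replicate 2 (median 0.08, adjusted p = 0.177). Of 24 TGF-beta and contractile genes, 8 rose and 2 fell at 12 h (8 and 2 adjusted over the list alone), with a list call at 12 h (adjusted p = 0.0444) that was lost with an estimated correlation (adjusted p = 0.383), and without DMSO replicate 2 (median 0.04, 0.177), 9 h replicate 1 (0.0512) or 2 (0.0510), or 12 h replicate 2 (0.0599), and with quantile normalization (0.282).

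The other lists were not called against DMSO at any time by camera. With fry, which sets members against no change rather than against other genes, NF-kB feedback genes were lower at 6 and 9 h (adjusted p = 0.000374 and 0.00392), cholesterol synthesis genes (0.0165) and fibroblast markers (0.00249) lower at 6 h, and reference housekeeping genes (0.0351) and endothelial markers (0.0238) lower at 12 h. Epithelial markers were higher at 9 and 12 h (0.00392 and 0.00390), immediate early genes at 6 and 12 h (0.0135 and 0.0351), and smooth muscle and pericyte markers at 12 h (0.0198), and fry also called TGF-beta and contractile genes higher at 6 h (0.0431), where the mean was 0.09 and the median −0.02. At 12 h the numbers that rose and fell were 3 and 4 of 13 NF-kB feedback genes, 5 and 2 of 30 interferon-stimulated genes, 3 and 6 of 25 cholesterol synthesis genes, and 12 and 3 of 30 immediate early genes, with the same counts adjusted over the list alone. They were 3 and 1 of 34 ribosomal protein genes (1 and 1 adjusted over the list alone), 1 and 4 of 15 reference housekeeping genes (1 and 4), and 7 and 3 of 20 fibroblast markers (7 and 4). Among markers of other cell types they were 3 and 1 of 8 epithelial, 0 and 2 of 7 endothelial, 0 and 0 of 3 immune, and 5 and 1 of 12 smooth muscle and pericyte markers, with the same counts adjusted over the list alone. Immediate early genes at 6 h were called without DMSO replicate 1 (adjusted p = 0.0298) or 12 h replicate 1 (0.0472) or 2 (0.0486). TGF-beta and contractile genes at 9 h were called without DMSO replicate 1 (0.0328), and smooth muscle and pericyte markers at 12 h without DMSO replicate 1 (0.0124) or 12 h replicate 2 (0.0458). Without a filter on low values immediate early genes at 6 h (0.0413) and smooth muscle markers at 12 h (0.0384) were called, the latter also with a mean of at least 50 (0.0379).

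**Figure D3:**
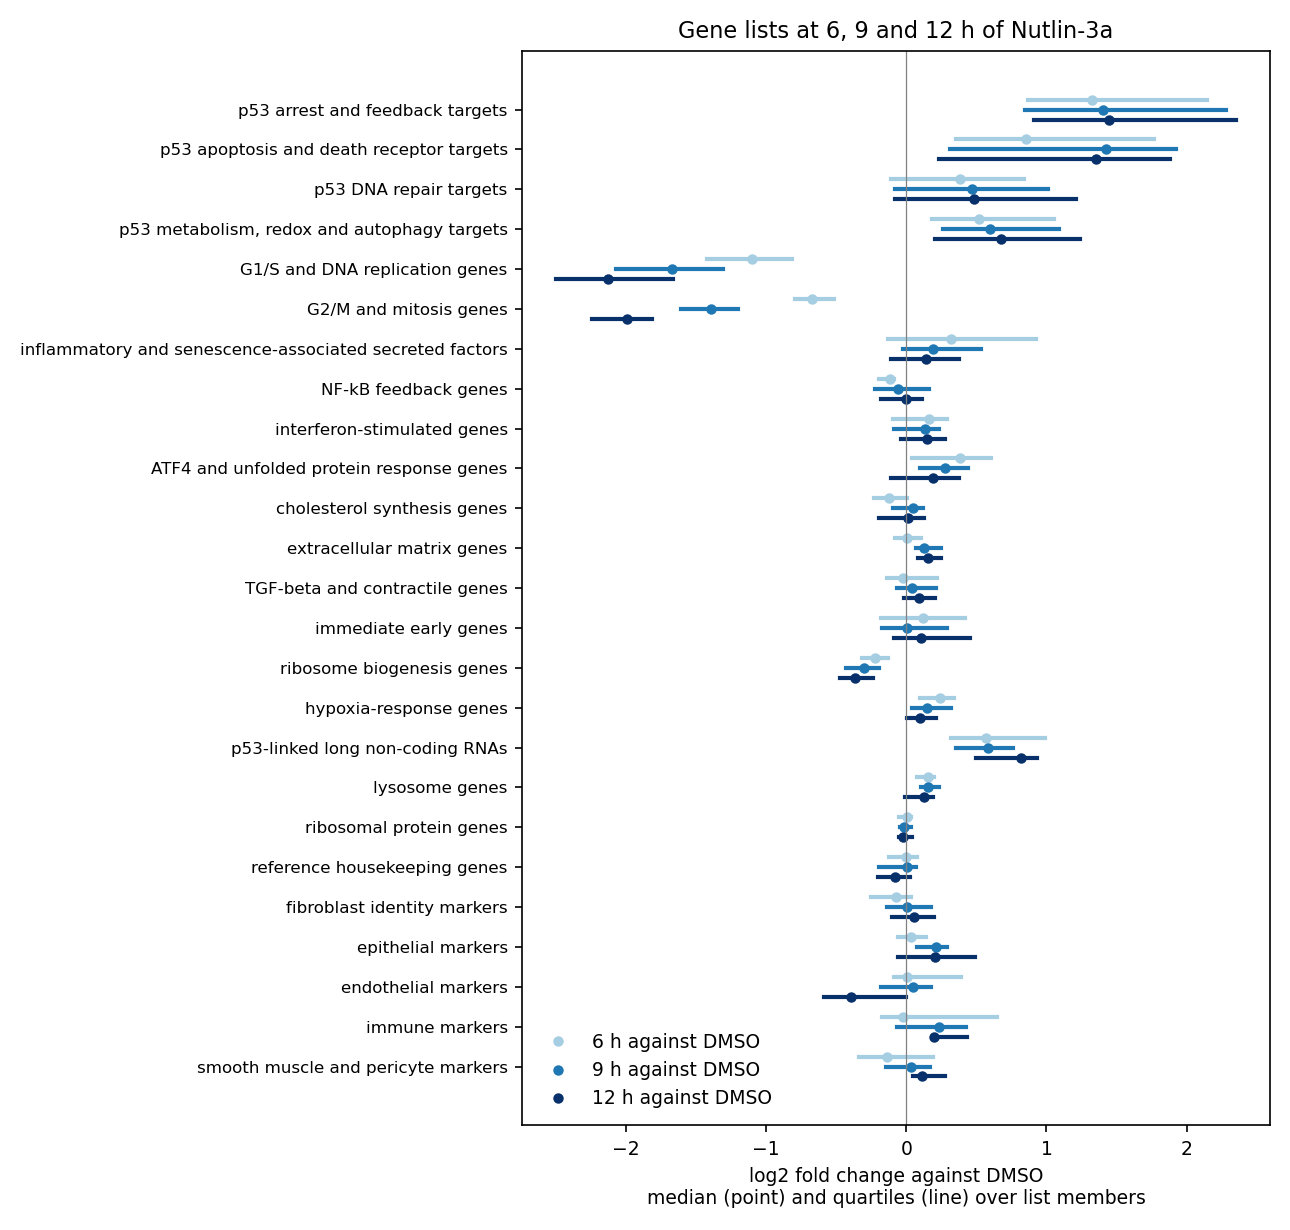
Median (point) and quartiles (line) of the log2 fold change against DMSO over the tested members of 25 gene lists at 6, 9 and 12 h. The G1/S and G2/M lists reach medians of −2.13 and −1.997 at 12 h, and the arrest and feedback targets of p53 1.45.

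The 3 comparisons with DMSO shared many genes, with 1107 that rose and 1777 that fell at all 3 times. At 6 and 9 h, 1386 genes rose and 1969 fell in both, where independent lists would share 365 and 554, and 67 went in opposite directions. At 6 and 12 h the numbers were 1229 and 1901 (independent 419 and 619), with 228 opposite, and at 9 and 12 h 1816 and 2352 (independent 420 and 575), with 10 opposite. Simulated unchanged groups shared 0 genes in 20 simulations. They hold no true change, so this 0 cannot show how many real calls the shared controls add. They also had the same spread in all groups, unlike the wider DMSO pair, so the simulated values below may be too low. The correlation across genes, which are not independent replicates, was 0.79 for 6 and 9 h (simulated 0.49), 0.70 for 6 and 12 h (0.50) and 0.91 for 9 and 12 h (0.52), and the covariances were 0.155, 0.157 and 0.221 (simulated 0.0166, 0.0167 and 0.0166). With 1 DMSO library for each comparison, a division chosen after the result was seen, 1170 or 1240 genes rose and 1751 or 1830 fell at both 6 and 9 h, with 254 or 130 opposite. For 6 and 12 h the numbers were 1089 or 1116 and 1724 or 1797, with 476 or 366 opposite, and for 9 and 12 h 1512 or 1475 and 2113 or 2119, with 62 or 79. Covariances were then 0.131 or 0.134, 0.133 or 0.135, and 0.199 or 0.198. With the pair so divided, independent lists would share 445 or 398 genes that rose and 634 or 586 that fell at 6 and 9 h. For 6 and 12 h these values were 495 or 445 and 687 or 657, and for 9 and 12 h 487 or 489 and 617 or 638. Each comparison then has a single control library, and part of the excess may still come from the controls. The counts for independent lists take all genes as equally likely to be called. Genes that are easy to call in any comparison would add to the excess.

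Between 6 and 12 h, cell-cycle genes fell further. Of the 24 arrest and feedback targets 6 rose and 6 fell (6 and 7 adjusted over the list alone), with a median of −0.06 (adjusted p = 0.941, camera). HJURP, a chaperone of centromeric histone, changed by −1.98 ± 0.07 from 6 to 12 h, CENPA, that histone itself, by −1.81 ± 0.11 and MKI67 by −1.67 ± 0.05. SULF2, which is on none of the lists, rose by 2.03 ± 0.14, CYFIP2 by 1.62 ± 0.09, TP53I3 by 1.07 ± 0.05 and CDKN1A by 0.43 ± 0.04, while GDF15 fell by 0.75 ± 0.06. BTG2 fell by 0.19 ± 0.06, a call lost without 6 h replicate 1 (−0.16) or 2 (−0.21) or 12 h replicate 1 (−0.19) or 2 (−0.18), with quantile normalization (−0.16) or without a trend (−0.19). MDM2 changed little (0.09 ± 0.06, adjusted p = 0.265), and was called without DMSO replicate 1 (adjusted p = 0.0380) or 2 (0.0374), with only the 2 groups (0.0467) or with GC correction (0.0273). In all, 2031 genes were higher and 2400 lower at 12 h than at 6 h (edgeR 2147 and 2326), 94 and 251 at least 2-fold. Without 12 h replicate 1, 1276 genes were higher, and without replicate 2, 1249.

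Among lists, 48 of 50 G1/S genes (48 adjusted over the list alone) and all 52 G2/M genes (52) fell from 6 to 12 h, with medians of −0.997 and −1.38, calls that held with an estimated correlation (adjusted p = 0.00223 and 0.00164). A further 7 lists were called by camera and lost this with an estimated correlation, which also uses fewer degrees of freedom. They were p53 targets in apoptosis (median 0.07, adjusted p = 0.338 with an estimated correlation) and metabolism (0.11, adjusted p = 0.257), extracellular matrix genes (0.10, adjusted p = 0.403), ribosome biogenesis genes (−0.15, adjusted p = 0.316), hypoxia-response genes (−0.14, adjusted p = 0.257), fibroblast markers (0.16, adjusted p = 0.257) and smooth muscle and pericyte markers (0.06, adjusted p = 0.402). Members that rose and fell were 7 and 4 of 21 for apoptosis, 8 and 1 of 20 for metabolism, 2 and 13 of 28 for hypoxia, and 5 and 1 of 12 for smooth muscle, with the same counts adjusted over the list alone. They were 15 and 1 of 35 for the matrix (15 and 2 adjusted over the list alone), 2 and 19 of 35 for ribosome biogenesis (2 and 20), and 9 and 4 of 20 for fibroblast markers (10 and 4). The apoptosis call was also lost without 6 h replicate 2 (adjusted p = 0.0709), the fibroblast call without 12 h replicate 1 (0.0556), and the smooth muscle call without 6 h replicate 1 (median 0.02, 0.0603) or 12 h replicate 1 (0.07, 0.0605). GC correction (0.0573 and 0.0871) and a replicate block (0.0514 and 0.0548) ended the apoptosis and smooth muscle calls, a mean of at least 50 the apoptosis and fibroblast calls (0.0553 each), and quantile normalization the fibroblast call (0.194). ATF4 and unfolded protein response genes (median −0.28, adjusted p = 0.0657) were called without DMSO replicate 1 (0.0213) or 2 (0.0191) or 12 h replicate 2 (0.0458) or without a filter (0.0249), and secreted factors with quantile normalization (0.0383). With fry, further lists were called, which were secreted factors (adjusted p = 0.00153), ATF4 genes (0.00136), lysosome genes (0.0245) and endothelial markers (0.00767) as lower, and NF-kB feedback genes (0.00249) and epithelial markers (0.0265) as higher.

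Some genes that had changed at 6 h turned back by 12 h. NR4A2, an orphan nuclear receptor, fell by 1.79 ± 0.16 at 6 h and rose by 2.54 ± 0.16 from 6 to 12 h, ending 0.74 above DMSO. PDE7B, a phosphodiesterase, fell by 1.72 ± 0.10 and rose by 2.41 ± 0.10. The chloride channel gene ANO1 rose by 1.40 ± 0.09 and fell by 1.89 ± 0.09, and ANGPTL4 rose by 2.51 ± 0.08 and fell by 1.63 ± 0.08. ANKRD1, a cardiac and stretch-responsive ankyrin repeat gene, rose by 1.60 ± 0.07 and fell by 1.88 ± 0.07, and its 12 h value below DMSO (−0.28 ± 0.07) was not called without 12 h replicate 1 (−0.18), with quantile normalization (−0.19) or without a trend (−0.28). In all, 798 genes rose at 6 h and fell from 6 to 12 h and 745 fell and then rose, 1543 together, of which 1063 were not called at 12 h against DMSO. Another 1019 genes went on in the same direction. Both comparisons use the 6 h libraries with opposite signs, so error in these libraries adds to the first count and takes from the second. Independent lists, which take all genes as equally likely to be called, would give 804 and 821 in the full fit. Simulated unchanged groups gave 0 that turned back, which says little, since they hold no true change. The 6 h libraries were also divided, after the result was seen. Independent lists would then give 431 that turned back and 445 that went on, or 413 and 429 the other way round. With 6 h replicate 1 used for the change at 6 h and replicate 2 for the change from 6 to 12 h, 907 turned back and 751 went on, and the other way round 912 and 719. Without 6 h replicate 1 the full set of 1543 became 986.

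**Figure D4:**
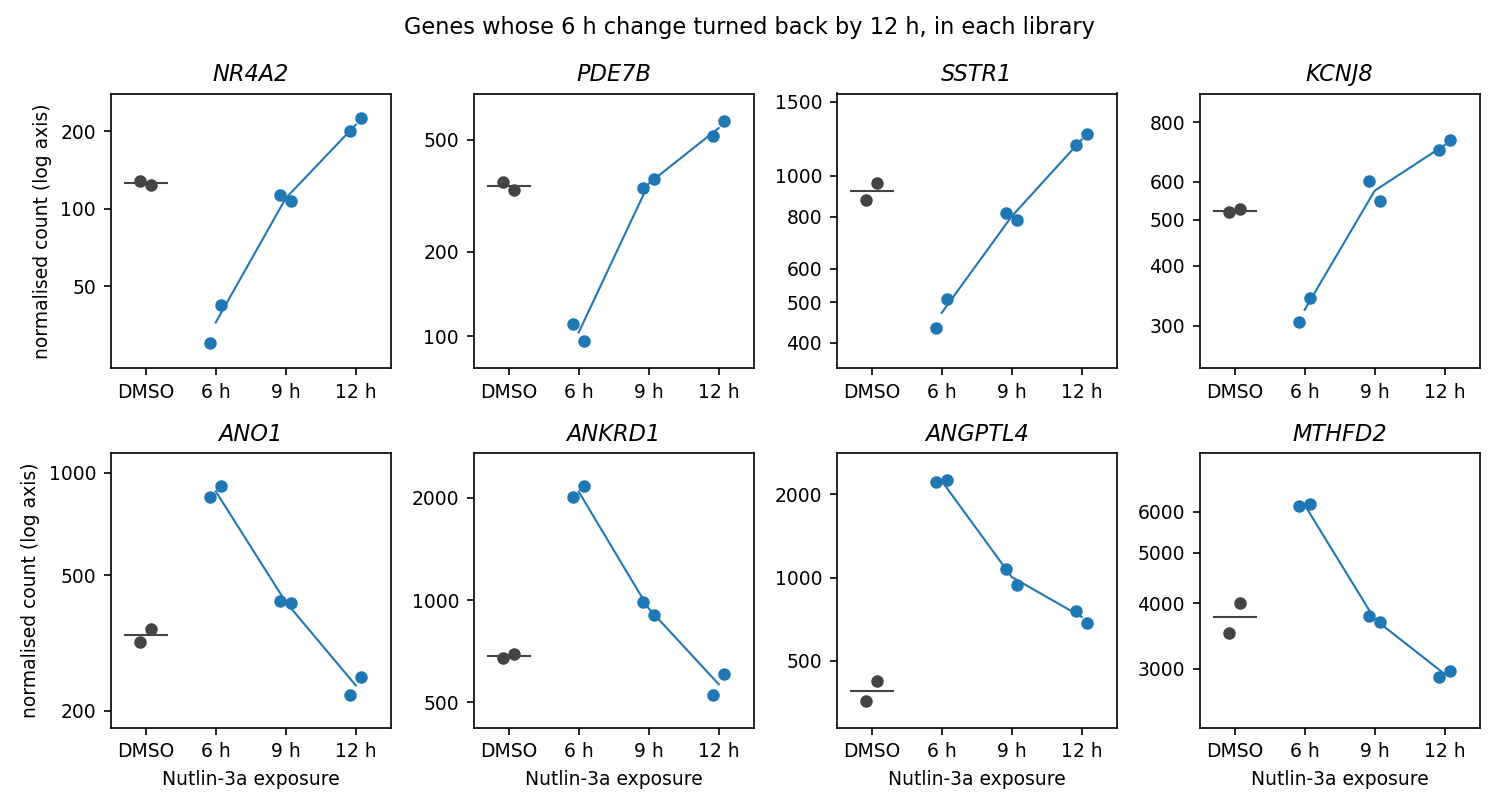
Normalized counts (log axis) of 8 genes in each library, by exposure, where points are libraries and lines join the means of Nutlin-3a groups. NR4A2 fell to a mean of 36.1 at 6 h and reached 212 at 12 h, and ANO1 rose to 881 and fell to 237.

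Over shorter steps fewer genes changed. From 6 to 9 h, 1199 genes rose and 1393 fell (edgeR 1234 and 1363). From 9 to 12 h, 152 rose and 411 fell (edgeR 186 and 386), and 0 rose and 2 fell at least 2-fold. Genes that rose were 27.0% of those called from 9 to 12 h, against 38.7% after GC correction. These counts moved when a library was left out, and leaving out either library of a pair gave similar counts. The DMSO libraries are not compared here and act through the spread that the fit shares among groups. From 6 to 9 h, genes that rose numbered 1880 and 1894 without DMSO replicate 1 or 2, 697 and 642 without 6 h replicate 1 or 2, and 579 and 581 without 9 h replicate 1 or 2. Genes that fell numbered 761 and 888 without 6 h replicate 1 or 2, and 845 and 769 without 9 h replicate 1 or 2. From 9 to 12 h, genes that rose numbered 438 and 446 without DMSO replicate 1 or 2, 58 and 57 without 9 h replicate 1 or 2, and 50 and 42 without 12 h replicate 1 or 2, and genes that fell 819 and 825, 213 and 227, and 237 and 224. Over all 4 groups, 7017 genes varied by the F test.

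Reads of overlapping genes cannot be told apart where the strand setting is unknown. Of the 141 named genes, 23 share exon sequence with a protein-coding gene on the other strand, and their values are uncertain to that extent. Those with values in this or the closing parts are CCNA2, CCNE2, CYFIP2, DNAJB9, FAS, FBN2, HJURP, HSPG2, KRT18, LIPA, MCM2, MDM2, MTHFD2, NPC1, SULF2, TNFRSF10B, TP53I11 and TP53I3.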

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

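In this part the GC, length, DMSO depth and clock tests and the use of different 6 h libraries were chosen after the result was seen, and the test without 6 h replicate 1 before.

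A difference between the effects at 12 and 6 h, tested in the same fit, marked 106 of the 136 named genes considered here and 9 lists. Of all 14074 tested genes 31.5% were called. The naming rule picked genes by their changes in these data, so a high share among them is built in. Of the 106 genes, 50 were higher and 56 lower at 12 h than at 6 h, as log2 changes. The largest of these increases were NR4A2 2.54, PDE7B 2.41, SULF2 2.03, CYFIP2 1.62, ANKEF1 1.41, SSTR1 1.37, BTBD11 1.37, SCN2A 1.36, INPP5D 1.22, KRT19 1.21, KCNJ8 1.15, TP53I3 1.07 and SPATA18 0.93. Next came BIRC3 0.84, TP53TG1 0.83, TNFRSF10C 0.80, FDXR 0.70, DNAJB9 0.70, WDR63 0.63, VWCE 0.62, HSPA5 0.60, APOBEC3C 0.58, HSPG2 0.56, ID2 0.56, RPS27L 0.56 and RRM2B 0.48. Smaller ones were FBN2 0.46, RRAD 0.46, KRT7 0.45, LIPA 0.44, CDKN1A 0.43, COL1A1 0.39, ID1 0.38, MEG3 0.38, DDB2 0.37, COL1A2 0.35, ID3 0.35, HERPUD1 0.32 and STAT2 0.31. The smallest were RRS1 0.27, CLDN4 0.27, CYLD 0.27, DDX58 0.25, COL5A1 0.24, NFKBIZ 0.23, SDHA 0.22, LTBP2 0.20, IL11 0.18, P4HA2 0.15 and DUSP1 0.15.

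The largest decreases were HJURP −1.98, ANO1 −1.89, ANKRD1 −1.88, CENPA −1.81, CDCA8 −1.81, E2F8 −1.80, SYT16 −1.80, SKA1 −1.78, ZNF367 −1.72, MKI67 −1.67, ANGPTL4 −1.63, ASPM −1.55, CCNE2 −1.52 and CCNA2 −1.43. Further down were FAM111B −1.41, RRM2 −1.35, WDR76 −1.32, MCM2 −1.25, MCM10 −1.24, DTL −1.22, MCM3 −1.15, MTHFD2 −1.08, MCM4 −1.07, VWF −1.03, FLT1 −0.95, CDC6 −0.95, ORC1 −0.84 and CDC25A −0.79. Smaller decreases were GDF15 −0.75, NPC1 −0.68, OAS3 −0.67, KRT18 −0.66, GLA −0.54, VEGFA −0.53, SIVA1 −0.43, HK2 −0.42, TEK −0.38, NDRG1 −0.38, HPRT1 −0.37, LIF −0.35, DDIT4 −0.32 and FANCC −0.32. The smallest decreases were NEAT1 −0.30, DKC1 −0.30, PHGDH −0.30, FOSL1 −0.29, NOP56 −0.25, EBP −0.24, ADM −0.22, NCL −0.20, PDGFRA −0.19, BTG2 −0.19, MYC −0.18, IER5 −0.17, NOTCH3 −0.14 and NOLC1 −0.14.

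Lists marked in the same way, with the median log2 change, follow. With an estimated correlation only G1/S and G2/M genes kept the call (adjusted p = 0.00223 and 0.00164), and the other 7 lost it (0.257 to 0.403). The lists were p53 targets in apoptosis (0.0732) and in metabolism (0.11), G1/S (−0.997) and G2/M genes (−1.38), extracellular matrix genes (0.10), ribosome biogenesis genes (−0.15), hypoxia-response genes (−0.14), fibroblast markers (0.16), and smooth muscle and pericyte markers (0.0635).

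Calls from 6 to 12 h that were lost without a library follow, with the log2 change. Without 12 h replicate 1 (adjusted p 0.0506 to 0.262) they were BTG2 −0.19, CLDN4 0.22, DUSP1 0.17, EBP −0.25, IER5 −0.11, IL11 0.19, LTBP2 0.16, MYC −0.18, NCL −0.16, NFKBIZ 0.26, NOLC1 −0.16, P4HA2 0.14, RRAD 0.44 and VWF −0.59. Without 12 h replicate 2 (0.0586 to 0.352) they were BTG2 −0.18, CLDN4 0.33, DDX58 0.20, DUSP1 0.12, EBP −0.23, IL11 0.16, MYC −0.17, NFKBIZ 0.21, NOLC1 −0.12, NOTCH3 −0.09, P4HA2 0.16, RRAD 0.47, SDHA 0.18, TNFRSF10C 0.73 and VWCE 0.54. Without 6 h replicate 1 (0.0539 to 0.258) they were BTG2 −0.16, CLDN4 0.29, DUSP1 0.14, EBP −0.30, FANCC −0.27, IL11 0.15, MYC −0.18, NOLC1 −0.16, NOTCH3 −0.10, P4HA2 0.11, PDGFRA −0.15, RRAD 0.39, SDHA 0.18, TNFRSF10C 0.75 and VWCE 0.53. Without 6 h replicate 2 (0.0557 to 0.226) they were BTG2 −0.21, CLDN4 0.25, DDX58 0.20, DUSP1 0.16, EBP −0.19, IER5 −0.15, IL11 0.20, LTBP2 0.17, MYC −0.17, NFKBIZ 0.17, NOLC1 −0.12 and VWF −0.69. Without 9 h replicate 1 (0.0521 to 0.0645) or 2 (0.0520 to 0.0645) they were DUSP1 0.15, NOLC1 −0.14 and NOTCH3 −0.14. Without DMSO replicate 1 or 2, calls were gained for CD68 0.21, MDM2 0.09, NFKB1 −0.15, RPS14 0.12, RPS15 −0.12, TFRC −0.15, TP53I11 −0.15 and TWIST1 0.22, and without 6 h replicate 2 for CD68 0.31.

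A share outside the gene counts also stood out. Reads in no annotated feature made up 6.10 and 6.04% of the 6 h libraries and 6.10 and 6.17% of the 12 h libraries, above both DMSO libraries (5.91 and 5.80%). The 9 h libraries had 6.00 and 5.90%.

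The 1543 genes that changed at 6 h and turned back by 12 h could reflect the lower depth of 6 h replicate 1. Without that library 986 genes met both tests, 943 of them in the full set, and 1094 did so without 6 h replicate 2, which is against depth as the whole cause, as 1717 genes with GC trends removed are against GC. With different 6 h libraries in the 2 comparisons 907 or 912 genes met both tests, where independent lists would give 431 or 413. Another 751 or 719 went on in the same direction, where independent lists would give 445 or 429. A low count, which would have spoken for error of single libraries, could therefore not come out. That more genes turned back than went on is still against such error as the whole cause. A change common to both 6 h libraries stays open. A list of 9 clock output genes had a median of −0.75 at 6 h, below all 10000 random lists of like expression (lowest −0.74), and 6 of the 9 turned back. The list was added after values had been seen. Random lists were drawn gene by gene, which does not allow for genes that move together, so this rank only describes the data. Harvest times are not given, so an effect of exposure time cannot be told from a clock phase or handling time that differed between groups.

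The wider spread of the DMSO pair (SD 0.147) was related to GC content. With the GC trend removed the SD was 0.131. In the 6, 9 and 12 h pairs it also dropped, from 0.0971, 0.0860 and 0.0880 to 0.0910, 0.0854 and 0.0847. With the length trend removed the SD of the DMSO pair was 0.147. Its chi-square per degree of freedom, which allows for counting error only, was 7.35. The DMSO libraries held 27.9 and 25.3 M gene reads, and the narrower 6 h pair 21.9 and 28.6 M. None of these accounts for the whole spread. GC accounts for part of it, and for part of the spread of the other pairs. No biological explanation was tested.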

How the results depend on the processing

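The alternatives were fixed before the data were seen, apart from GC correction, group weights and the divisions of the DMSO pair and of the 6 h pair, which were chosen after the result was seen. For named genes and lists, reversed meant a change of sign with a call in the main or the alternative fit. No value was so classed. Moved meant for them a change of sign with a call in neither fit. Counts had no class for a reversal. The balance of genes that rose and fell did turn under some alternatives. In the main test more genes fell than rose in each comparison. More rose than fell in some comparisons with quantile normalization, TMM and GC correction, as given below. This was also so with edgeR at 12 h (3006 and 2817), and with quantile normalization from 6 to 9 h (1269 and 1247). Of 278 counts 240 stayed within 1.5 times the main count and 38 moved. Of 12251 values for 564 comparisons of named genes 11810 kept sign and call, 275 lost the call, 107 gained a call and 59 moved. Of these comparisons 111 changed call under some alternative, 27 of them only with a library left out. For lists, of 1796 values 1652 kept sign and call, 57 lost the call, 32 gained a call and 55 moved, and 46 of 100 comparisons changed call. These classes do not compare the sizes of the changes. Where no reason is given, the cause was not tested.

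Without an intensity trend, 597 genes rose and 740 fell from 6 to 9 h, and 30 rose and 144 fell from 9 to 12 h. With only the 2 groups compared, 530 rose and 857 fell from 9 to 12 h, with group weights 428 and 812, and with GC correction 300 rose. With DESeq2 786 rose from 6 to 9 h. Quantile normalization fixes the top ranks by its construction, so COL1A1 had 0.00 at 9 and 12 h and COL1A2 0.10 at both, and from 6 to 12 h both had 0.00. With it more genes rose than fell at 9 h (2770 and 2280, 54.9% against 45.8% as deposited), at 12 h (3369 and 2482) and from 6 to 12 h (2315 and 2113). The same turn came with TMM at 9 h (2550 and 2491) and 12 h (2969 and 2779), and with GC correction at 9 h (2843 and 2722), 12 h (3397 and 2883) and from 6 to 12 h (2538 and 2364). A value of COL1A1 that differed from 0 only by rounding error was set to 0.

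With a library left out, which is a smaller sample, the number of genes that rose was 1494 to 2683 at 6 h, 1419 to 2640 at 9 h, 1699 to 2947 at 12 h, 579 to 1894 from 6 to 9 h, 42 to 446 from 9 to 12 h and 1249 to 2674 from 6 to 12 h. The number that fell was 2136 to 3189, 2002 to 2866, 2339 to 3216, 761 to 2042, 213 to 825 and 1682 to 3002, and 5849 to 8229 varied by the F test.

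The labels give replicates only a number. Between groups, deviations of libraries with the same number had correlations of −0.03 to 0.03 over all genes and −0.23 to 0.16 over genes with a mean of at least 200 (DMSO with 6 h −0.23, with 9 h 0.11 and with 12 h 0.16, and 9 with 12 h 0.13). With the replicate number as a block, 2269 genes rose and 2892 fell at 6 h, 2277 and 2674 at 9 h, 2616 and 2993 at 12 h, 1189 and 1398 from 6 to 9 h, 145 and 405 from 9 to 12 h, and 2041 and 2392 from 6 to 12 h, and 6983 varied. In that fit SSTR1 (adjusted p = 0.0401) and RPS12 (0.0273) were called at 9 h, and the apoptosis (0.0514) and smooth muscle lists (0.0548) were not called from 6 to 12 h.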

Other observations

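The gene span test in this part was set before the result was seen, and the clock list was chosen after the result was seen.

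Some lists that camera did not call against DMSO held members that moved in opposite directions. Among immediate early genes, MYC (−0.66, −0.72 and −0.84 at 6, 9 and 12 h) and FOSL1 (−0.33, −0.54 and −0.63) fell, while the phosphatase gene DUSP1 (0.38, 0.46 and 0.52) and IER5 (0.66, 0.46 and 0.49) rose. Among NF-kB feedback genes BIRC3, an inhibitor of apoptosis, fell (−1.45, −0.73 and −0.60) and NFKBIZ, an IkB-like regulator, rose at 12 h (0.34). Among interferon-stimulated genes OAS3 fell (−0.55, −0.87 and −1.22) and STAT2 rose at 9 and 12 h (0.35 and 0.40). Among cholesterol synthesis genes 11 fell and 3 rose at 6 h (12 and 3 adjusted over the list alone), and STARD4, a sterol carrier, rose (0.75, 0.75 and 0.64). Of 20 fibroblast markers 7 rose and 3 fell at 12 h (7 and 4 adjusted over the list alone). PDGFRA (−0.25, −0.43 and −0.44) and TWIST1 (−0.79, −0.71 and −0.57) fell, while COL1A1 (0.26 and 0.32) and COL1A2 (0.26 and 0.34) rose at 9 and 12 h, calls that quantile normalization ended. The keratin gene KRT7 rose at 9 and 12 h (0.34 and 0.58), and KRT18 rose at 6 h (0.40) and was below DMSO at 12 h (−0.26).

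Clock output genes, a list of 9, were all lower at 6 h (9 called, 9 adjusted over the list alone, median −0.75). Of them 4 were lower at 9 h (4), and 1 was higher and 1 lower at 12 h (1 and 1). NR1D1, a repressor in the clock, had log2 changes of −0.78, 0.16 and 0.53 at 6, 9 and 12 h, where the 9 h value was not called (limma, adjusted p = 0.289). From 6 to 12 h 6 of the 9 rose (9 adjusted over the list alone).

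A hypothesis that long genes rise later because they take longer to transcribe was tested. The correlation (Spearman) of the change from 6 to 12 h with gene span was 0.0271 in 2557 genes higher at 12 h than in DMSO and 0.0252 in 8079 genes not called, a difference of 0.00192. Between 6 and 12 h, span was thus no more related to the change in the risen genes than in uncalled ones. The first sample was taken at 6 h, so a delay that had ended by then could not show here.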
